A study of Mus musculus with 6 samples.

How the data were processed

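Total RNA from 6 BMMC samples, 3 naive and 3 taken 4 h after ionomycin, was measured on whole-transcript Affymetrix arrays with biotin-labelled targets, per the labels. The values used are the authors' processed values, deposited as log2 signals, 65770 rows by 6 arrays with 0 missing values. Per the submitters' processing notes they were made with the R package oligo; its version, the summarization, the normalization and the genome build are not given in the sources used here. Scanner files were not used here. That the scale is log2 was read from the values, which run from 3.01 to 14.6; whether and how the authors centred or scaled arrays stays unknown, since the columns' quantiles are close but unequal. Their medians are 5.88, 5.96 and 5.99 for naive replicates 1, 2 and 3 and 5.96, 6.03 and 6.03 for ionomycin replicates 1, 2 and 3, a mean shift of 0.07 between groups. The normalization can move small differences by about that size: the median log2 difference of all genes is 0.05 as deposited, 0.01 after quantile normalization and -0.01 after centring.

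Rows were named through the platform annotation: 30439 rows have 1 gene symbol, 2146 several and 33185 none, and rows with several name no gene here. Symbols of 827 rows were updated through Entrez IDs with RefSeq genes of assembly GRCm38.p6, among which 22763 rows with 1 symbol were found. That assembly was used for names and neighbours only, and no coordinates are given. Of the 252 genes with several rows, the row with the highest mean over the 6 arrays was kept, which left 30102 genes. Among called genes 2, Cflar and Idi2, had 2 rows each, and both rows of each gene differed in the same direction. Background was set at the 95th percentile of the 6-array means of 1752 chemosensory receptor genes, which mast cells have little reason to express, a log2 level of 5.99; 19200 genes had a mean above it. No pair of arrays held identical values.

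Groups and replicate numbers come from the sample titles. Ionomycin was compared with naive in limma 3.58.1 (lmFit and eBayes, R 4.3.3, with version 1.17.8 of data.table) over all 6 arrays without a block or a filter on dim rows, two-sided, with Benjamini-Hochberg adjustment over the 30102 genes and a threshold of 0.05; every adjusted p for a gene is from limma. Differences are ionomycin minus naive, fold changes are 2 to the power of the log2 difference, and errors are moderated standard errors (SE) or standard deviations (SD). The threshold, tests, lists and named-gene rule were fixed before the data were examined. Gene lists were tested with camera, with its preset correlation of 0.01, and adjusted over the 31 lists with at least 5 measured members, of 32 lists; 803 of 892 list genes were measured. A camera test sets a list against all other genes, so its direction can differ from the sign of the list's median: median and mean differ in sign for 5 lists (calcium and NFAT, cholesterol synthesis, unfolded protein response, ribosome biogenesis, lysosome). With the correlation estimated from the data, 0 of the 31 lists passed in camera (smallest adjusted p = 0.0553), with 3 higher and 2 lower at an unadjusted p under 0.05. In that setting camera also takes its degrees of freedom from the 6 arrays and not from the number of genes. Its p-values can therefore rise without a higher correlation. The estimated correlation was -0.0426 for heat shock and 0.0111 for mast cell receptors and identity factors, against the preset 0.01. By fry, 13 rose and 2 fell, with eicosanoid synthesis gained (adjusted p = 0.0371) and the interferon list lost (0.105) among those that rose.

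Named genes follow a rule of 3 parts. The 12 largest rises and 12 largest falls were taken among genes past the threshold, with no overlap between the groups and above background in the higher group, leaving out unnamed or predicted genes, small RNAs and immunoglobulin or T cell receptor segments. From each list, up to 4 past members with the largest change were taken, and where fewer than 2 passed, the brightest members until 2 were named. In every case 13 genes were named (Kit, Fcer1a, Ms4a2, Cpa3, Hdc, Il4, Il6, Il13, Tnf, Ccl3, Nr4a1, Egr1 and Rcan1). This gave 95 genes.

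Replicate numbers in the titles are shared between groups, and the data were checked for pairing through the correlation, across genes, of deviations from the group means. It was 0.711, 0.476 and 0.469 for the same numbers 1, 2 and 3, all above 0.1, so the fit with the number as a block is given beside results it changes. The pairing is mostly that of replicate 1: the crossed correlations of numbers 2 and 3 were as high (0.481 and 0.524), and the difference between replicates 2 and 3 did not correlate between the groups (-0.0467).

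Alternatives were the replicate block, quantile normalization, centring of arrays on their median, a filter on dim genes, eBayes with trend and robust settings, array weights, the mean of a gene's rows, all rows as the tested set, a t statistic without moderation, each array left out in turn, an estimated correlation in camera, and fry. Leaving out both replicate 1 arrays, a block of 2 levels (replicate 1 against 2 and 3) and the block joined to an estimated correlation were added after seeing the data. The fits were tested on simulated data for the same comparison: 30102 genes with the real naive means and the residual spread of the blocked fit, 200 of them changed, in 5 simulations. Without an offset between replicates, limma without the block recovered 98.8% of changes of log2 1 and 99.8% of log2 2, with 13 false calls on average. In a further setting the mean offset of replicate 1 over both groups was added alike to both replicate 1 arrays. There limma recovered 74.6% and 93.0% without the block (0.8 false calls) and 98.2% and 99.8% with it (15.8 false calls). A block removes an offset that both groups share in full, so its recovery was built in. The real offset differed between groups (G2/M median 2.50 in naive and 1.76 in ionomycin cells). Camera on simulated arrays called the 1 shifted list (by log2 0.5) and 0 of the others. Those arrays had noise drawn independently for each gene and no offset between replicates. They cannot show how often camera calls a list falsely where its genes correlate, as in the real G2/M list (estimated correlation 0.907). Figures were drawn with matplotlib 3.10.9.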

Results

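Whole-transcript Affymetrix arrays measured total RNA from mouse bone marrow-derived mast cells (BMMCs), a primary culture in which C57BL/6J marrow is matured into mast cells with interleukin 3 and stem cell factor, here for 6 weeks. Ionomycin is an ionophore that lets calcium into the cell and makes mast cells release their granules. The activated cells received 1 µg/mL ionomycin in buffer for 1 h and the naive cells received buffer alone. Both groups then spent 3 h in culture medium, so RNA was taken 4 h after activation began. The comparison asks which transcripts differ at a time later than the first minutes, when granules are released. Each group had 3 arrays. The labels do not say that the 3 replicates came from separate cultures or animals. Every p-value for a gene therefore measures the spread between these samples, which may be technical. Camera at its preset correlation takes its error from the spread between genes, so its p-values for gene lists do not measure the spread between samples.

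Values are log2 signals, and the number of arrays limits their precision. Across genes, Pearson's r between arrays ran from 0.980 (naive replicate 1 against ionomycin replicate 3) to 0.998 (ionomycin replicates 2 and 3). The replicate 1 arrays of both groups stood apart: the first principal component, with 52.6% of the variance, put them at -48.0 (naive) and -21.2 (ionomycin) and the other 4 arrays between 13.0 and 21.9. The second component, with 31.9%, separated the groups, with naive arrays at -15.5, -24.7 and -16.4 and ionomycin arrays at 31.3, 14.3 and 10.9.

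At 4 h after ionomycin, the largest rises among the genes that the naming rule takes were those of Rln3, Ptgs2, Hspa1a and Tnip3. Rln3, which encodes the peptide hormone relaxin-3, went from 8.38 ± 0.79 to 12.98 ± 0.29 (log2 signal, SD, n = 3 per group), a 24.3-fold rise (log2 difference 4.60 ± 0.39 SE, limma adjusted p = 0.0153). Ptgs2, the inducible cyclooxygenase, rose 9.20-fold, from 8.71 ± 0.48 to 11.91 ± 0.72 (limma adjusted p = 0.0485), and Hspa1a, an inducible HSP70 chaperone, rose 8.71-fold, from 10.61 ± 0.55 to 13.73 ± 0.04 (adjusted p = 0.0153). Tnip3, named for an interaction of its product with A20, rose 7.14-fold (log2 2.84 ± 0.14, limma adjusted p = 0.00363). Falls were smaller, and the largest was that of Cd180, a surface protein related to Toll-like receptors, which fell 2.01-fold, from 10.53 ± 0.16 to 9.53 ± 0.10 (adjusted p = 0.0253).

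The other 8 of the 12 largest rises began with Slc37a2, a sugar phosphate transporter (log2 2.71), the lysosomal protease gene Ctsl (2.51) and the growth factor gene Hbegf (2.48). Then came the retinoic acid-binding protein gene Crabp2 (2.44), the small GTPase gene Rrad (2.40), Penk, the precursor of enkephalins (2.35), and the chaperone genes Hsph1 (2.19) and Hspb1 (2.01). Of these, Hbegf passed without the replicate number as a block (limma adjusted p = 0.0451) and not with it (0.0557). After Cd180, the other 11 largest falls were Kcne3, a potassium channel subunit (log2 -0.90, adjusted p = 0.0153), Pdcd4 (-0.79), Nfe2 (-0.73), Rgs12 (-0.69), Inpp5d, the lipid phosphatase SHIP1 (-0.64), Rin3 (-0.63), Fbxl4 (-0.61), Gna14 (-0.60), Dnm3 (-0.56), Mknk1 (-0.53) and Pacc1 (-0.46). With the replicate number as a block, limma's adjusted p was 0.0540 for Pdcd4, 0.0702 for Inpp5d, 0.0623 for Rin3, 0.0674 for Gna14, 0.0702 for Mknk1 and 0.0589 for Pacc1, so these 6 falls did not pass in that fit.

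**Figure D1:**
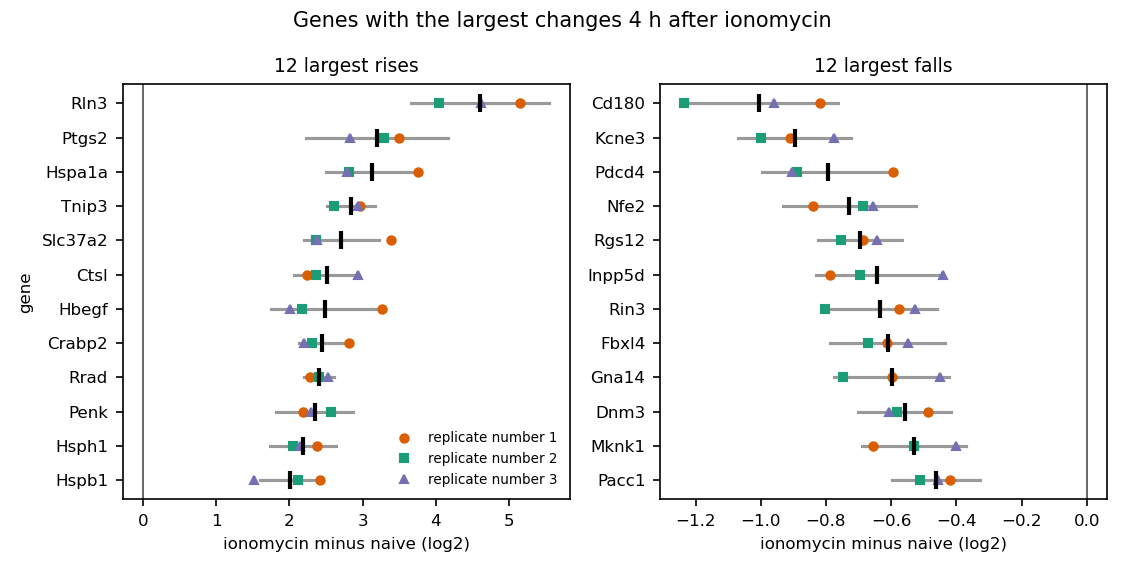
Difference between ionomycin and naive arrays (x axis, log2) for the 12 largest rises and 12 largest falls (y axis, genes) among genes past the threshold that the naming rule takes. Coloured points are the differences at each replicate number, black ticks the fitted difference and grey lines its 95% confidence interval. For every gene, from Rln3 at 4.60 downwards, all 3 points lie on the same side of 0. The naming rule forces this, since it takes only genes without overlap between the groups.

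Over all 30102 genes, 87 were higher and 18 lower at 4 h (limma, adjusted p under 0.05), of which 39 were at least 2-fold higher and 1, Cd180, at least 2-fold lower. All 105 showed the same direction at all 3 replicate numbers and no overlap between the groups' arrays. With 3 arrays per group a gene whose groups overlap cannot reach this threshold, so this follows from the calls and is no separate support. Over all genes the groups did not overlap for 26.2%, against 10% by chance for 3 exchangeable arrays against 3. The arrays were not exchangeable, since replicate 1 stood apart in both groups, so the share without a treatment effect may differ from 10%. With the replicate number as a block, 119 genes were higher and 33 lower, 62 and 2 of them at least 2-fold, and 63 of the higher and 8 of the lower genes were called in both fits. Without both replicate 1 arrays, a setting chosen after seeing the data, 423 genes were higher and 429 lower. Centring every array on its median moved the split from 82.9% higher calls to 68.3% (69 higher, 32 lower). The counts also depended on single arrays. Without 1 array they ranged from 1 gene higher and 0 lower (without ionomycin replicate 2) to 95 higher and 55 lower (without naive replicate 1). They were 13 and 0 without naive replicate 2, 8 and 1 without naive replicate 3, 35 and 0 without ionomycin replicate 1, and 7 and 0 without ionomycin replicate 3. Of the 39 named genes past the threshold only Rrad passed in all 6 such fits.

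Of the 19 measured members of the heat shock list, which holds cytosolic and mitochondrial chaperones and their partners, 8 rose, 0 fell and 11 did not pass. With the replicate block 6 rose over all genes. In this list 11 rose when adjusted over the list alone, and 17 were higher at all 3 replicate numbers. Besides Hspa1a, the strongest members were Hsph1, an HSP110 chaperone (4.55-fold, from 10.16 ± 0.34 to 12.34 ± 0.19, SD, n = 3, limma adjusted p = 0.0153), Hspb1, a small heat shock protein (4.04-fold, adjusted p = 0.0153), and Bag3, a partner of HSP70 (log2 1.40 ± 0.16, adjusted p = 0.0395, and 0.0536 with the block). The median member was 0.73 higher on the log2 scale. As a group the list rose against all other genes (camera adjusted p = 3.13e-10; adjusted p = 0.0553 with an estimated correlation). The row used for Hspa1a cannot exclude transcripts of its near-identical neighbour Hspa1b, which had no row naming it alone.

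**Figure D2:**
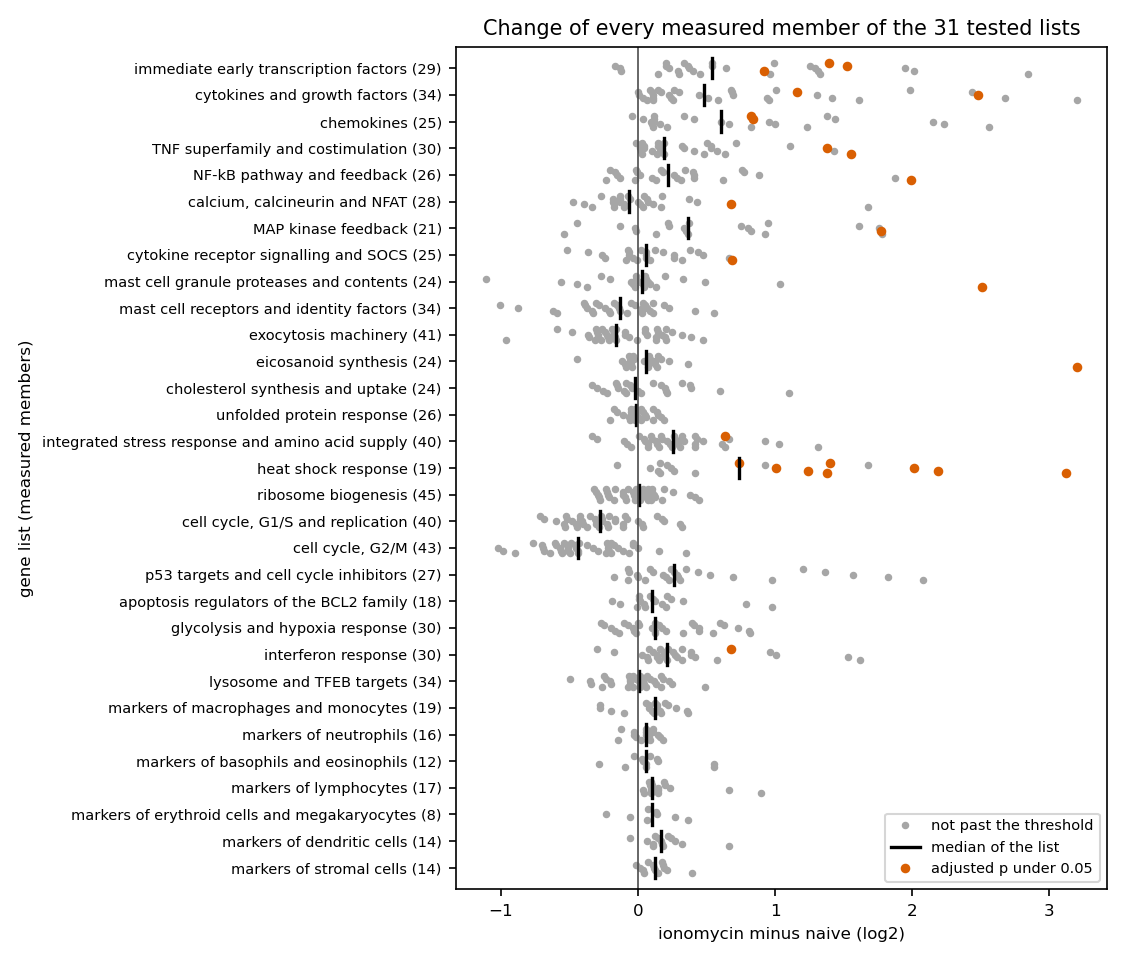
Difference between ionomycin and naive arrays (x axis, log2) for each measured member of the 31 tested gene lists (y axis, with the number of members). Orange points are members with a limma adjusted p under 0.05, grey points the others, and black ticks each list's median; the heat shock list holds 8 orange points and the highest median, 0.73.

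Of 34 measured cytokine and growth factor genes, 2 rose, 0 fell and 32 did not pass, while 15 rose when adjusted over the list alone. With the replicate block 5 rose over all genes. The 2 that rose were Hbegf and Csf1, the macrophage colony-stimulating factor (log2 1.16 ± 0.05, limma adjusted p = 0.00363). Il13, a type 2 cytokine of mast cells, was at 9.34 ± 1.22 in naive and 12.55 ± 0.73 in ionomycin arrays (log2 3.21 ± 0.66 SE, limma adjusted p = 0.132) and passed with the block (adjusted p = 0.0305), with differences of 2.63, 3.53 and 3.45 at the 3 replicate numbers. Il6 likewise passed with the block and not without it (log2 1.61 ± 0.44, limma adjusted p = 0.214 without and 0.0332 with it), and Tnf (2.43 ± 0.83, adjusted p = 0.273) and Il4 (0.69 ± 0.15, adjusted p = 0.153) passed in neither fit. With a block of 2 levels (replicate 1 against 2 and 3), chosen after seeing the data, Tnf (adjusted p = 0.0324) and Il4 (0.0116) passed as well. The list as a group rose (camera adjusted p = 1.62e-08; adjusted p = 0.270 with an estimated correlation).

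Of 25 measured chemokines, 2 rose, 0 fell and 23 did not pass, 15 rose when adjusted over the list alone, and 6 rose over all genes with the block. Ccl1, a ligand of CCR8, rose by 0.83 ± 0.06 on the log2 scale (limma adjusted p = 0.0114) and Cxcl10, an interferon-inducible chemokine, by 0.84 ± 0.10 (adjusted p = 0.0395), the latter from a naive mean of 5.63, below the background level of 5.99. Ccl3 had the larger difference of 2.23 ± 0.44 but did not pass (limma adjusted p = 0.118, 0.0693 with the block and 0.0151 with the block of 2 levels). The group rose (camera adjusted p = 1.54e-09; adjusted p = 0.153 with an estimated correlation).

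Some immediate early transcription factors and feedback regulators rose at 4 h. Of 29 measured immediate early genes, 3 rose, 0 fell and 26 did not pass, 20 rose when adjusted over the list alone, and 6 rose over all genes with the block. Jun, an AP-1 subunit, rose by 1.40 ± 0.14 (limma adjusted p = 0.0242). Atf3 (1.52 ± 0.18, adjusted p = 0.0395) and Zfp36, which destabilises cytokine mRNA (0.92 ± 0.11, adjusted p = 0.0417), rose without the block and not with it (adjusted p = 0.0653 and 0.0702). Nr4a1 (2.01 ± 0.39, limma adjusted p = 0.113) and Egr1 (0.99 ± 0.37, adjusted p = 0.292) passed with the block and not without it (adjusted p = 0.0410 and 0.0322). As a group the list rose (camera adjusted p = 7.05e-10; adjusted p = 0.270 with an estimated correlation).

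Among 21 measured genes of MAP kinase feedback, 1 rose, 0 fell and 20 did not pass. Adjusted over the list alone 11 rose and 2 fell, and with the block 3 rose over all genes. The gene that rose was Dusp1, a MAP kinase phosphatase (log2 1.78 ± 0.19, limma adjusted p = 0.0316), while Ier3, the brightest member, differed by 0.23 (adjusted p = 0.221). The group rose (camera adjusted p = 9.08e-05; adjusted p = 0.270 with an estimated correlation). Of 26 genes of the NF-kB pathway, 1 rose and 25 did not pass. Map3k8, the kinase Tpl2, rose by 1.99 ± 0.17 (limma adjusted p = 0.0153). Tnfaip3, which encodes A20, differed by 0.78 ± 0.27 (limma adjusted p = 0.275, 0.103 with the block and 0.0389 with the block of 2 levels). Over the NF-kB list alone 7 rose and 0 fell, against 11 and 2 with the block, where 3 rose over all genes. The NF-kB group rose (camera adjusted p = 0.0354; adjusted p = 0.271 with an estimated correlation), but not without naive replicate 3 (adjusted p = 0.104) or with array weights (0.0619).

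In the list of TNF superfamily and costimulatory genes, 2 of 30 measured members rose, 0 fell and 28 did not pass. When adjusted over the list alone 7 rose, and 12 with the block. Tnfsf10, the death ligand TRAIL, rose by 1.55 ± 0.16 (limma adjusted p = 0.0285), and Tnfsf4, the OX40 ligand, by 1.38 ± 0.12 (adjusted p = 0.0167). The group rose (camera adjusted p = 0.000150; adjusted p = 0.448 with an estimated correlation). Among 25 genes of cytokine receptor signalling, Jak2 rose by 0.69 ± 0.09 (limma adjusted p = 0.0485) and 24 did not pass, among them Il4ra (-0.52, adjusted p = 0.177). Over this list alone 3 rose and 1 fell, against 5 and 4 with the block. The group did not pass (camera adjusted p = 0.952), and its median of 0.06 turned to -0.01 after centring.

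Kit, the stem cell factor receptor, was at 13.16 ± 0.09 in naive and 12.77 ± 0.19 in ionomycin arrays (log2 -0.39 ± 0.11 SE, limma adjusted p = 0.222). The IgE receptor subunit genes Fcer1a (-0.05, limma adjusted p = 0.627) and Ms4a2 (-0.62 ± 0.14, adjusted p = 0.163) did not pass. For Ms4a2 limma's adjusted p was 0.0557 with the block and 0.0102 with the block of 2 levels. Cpa3, the mast cell carboxypeptidase (-0.04, adjusted p = 0.796), and Hdc, which makes histamine (1.04 ± 0.25, adjusted p = 0.180), did not pass either. Of 34 measured mast cell receptors and identity factors, 0 passed by limma, 3 were higher and 12 lower at an unadjusted p under 0.05, and over the list alone 1 rose and 6 fell (2 and 7 with the block). As a group this list fell (camera adjusted p = 2.9e-05; adjusted p = 0.153 with an estimated correlation), with a median of -0.13 and its brightest members Lilrb4a and Lilr4b at 0.04 and 0.08 (adjusted p = 0.777 and 0.544; Lilrb4a -0.03 after centring).

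Of 24 granule proteases and contents, 1 rose and 23 did not pass, and over the list alone 2 rose and 1 fell (4 fell with the block). The member that rose was Ctsl (5.70-fold, from 8.38 ± 0.31 to 10.89 ± 0.23, limma adjusted p = 0.0153), a protease of lysosomes rather than a mast cell-specific one. The group did not pass (camera adjusted p = 0.297), except without ionomycin replicate 1, where it fell (adjusted p = 0.0295), and its median of 0.03 turned to -0.02 after quantile normalization and -0.04 after centring. In the exocytosis list, 0 of 41 members passed by limma, 6 were higher and 11 lower at an unadjusted p under 0.05, and 3 fell when adjusted over the list alone (2 rose and 5 fell with the block). The exocytosis group fell (camera adjusted p = 0.000144; adjusted p = 0.162 with an estimated correlation), with a median of -0.16, while its brightest members Rab7 and Rab5a were at 0.05 and 0.13 (adjusted p = 0.797 and 0.356; Rab7 -0.01 after centring).

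Of 28 measured calcium and NFAT pathway genes, Atp2b1, a calcium pump of the plasma membrane, rose by 0.68 ± 0.08 (limma adjusted p = 0.0446, and 0.0662 with the block), and the other 27 did not pass. Among them were Rcan1, a calcineurin regulator (1.68 ± 0.59, limma adjusted p = 0.280), and Atp2a3 (-0.17, adjusted p = 0.322). For Rcan1 limma's adjusted p was 0.0807 with the block and 0.0247 with the block of 2 levels. Over the list alone 2 rose and 2 fell, against 4 and 4 with the block. Camera put the group barely past the threshold as lower (adjusted p = 0.0478; adjusted p = 0.498 with an estimated correlation, 0.0685 with the block), although its median was -0.06 and its mean 0.03. It did not pass without naive replicate 1 (adjusted p = 0.152) or 2 (0.149), ionomycin replicate 2 (0.127) or 3 (0.174), nor under either other scaling (0.308 after quantile normalization, 0.163 after centring). Nor did it pass among genes above background (0.180), with camera's trend setting (0.0675), with the block of 2 levels (0.0774) or by fry (0.847). Of 24 genes of eicosanoid synthesis, Ptgs2 alone rose and 23 did not pass, among them Alox5ap (-0.12, limma adjusted p = 0.376). Over the eicosanoid list alone 1 rose, and the group did not pass by camera (adjusted p = 0.714) but rose by fry (adjusted p = 0.0371), with a median of 0.06 that was -0.008 after centring.

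Among stress and amino acid supply genes of the integrated stress response, 1 of 40 rose and 39 did not pass. Ppp1r15a, a phosphatase subunit that reverses eIF2 phosphorylation, rose by 0.63 ± 0.07 (limma adjusted p = 0.0417, and 0.0683 with the block), and the brightest member, Slc3a2, was at -0.05 (adjusted p = 0.754). Over the list alone 2 rose, and 18 with the block. The group rose (camera adjusted p = 0.00622; adjusted p = 0.433 with an estimated correlation), but not without naive replicate 3 (adjusted p = 0.132) or ionomycin replicate 1 (0.0627). Of the unfolded protein response, 0 of 26 genes passed by limma, 1 was higher and 1 lower at an unadjusted p under 0.05, and the group did not pass (camera adjusted p = 0.258). The endoplasmic reticulum chaperones Calr and Hsp90b1 were at -0.02 and -0.05 (adjusted p = 0.920 and 0.655).

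Of 27 p53 targets and cell cycle inhibitors, 0 passed by limma, 14 were higher and 0 lower at an unadjusted p under 0.05, and 10 rose when adjusted over the list alone. Cdkn1a and Ccng1 were at 0.18 and -0.06 (adjusted p = 0.633 and 0.732). This group rose (camera adjusted p = 0.000375; adjusted p = 0.271 with an estimated correlation). Of 30 interferon response genes, Gbp3 rose by 0.68 ± 0.09 (limma adjusted p = 0.0485, and 0.0704 with the block) and 29 did not pass, among them Bst2 (0.06, adjusted p = 0.849, and -0.003 after centring). Over the list alone 9 rose, and with the block 14 rose and 1 fell. The interferon group rose (camera adjusted p = 0.000180; adjusted p = 0.525 with an estimated correlation), but not by fry (adjusted p = 0.105). Of 18 BCL2 family genes, 0 passed by limma and 2 were higher and 0 lower at an unadjusted p under 0.05, with Mcl1 at 0.01 (-0.05 after centring) and Bnip3 at 0.33 (adjusted p = 0.900 and 0.765). The BCL2 group did not pass (camera adjusted p = 0.272).

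In the lysosome list, 0 of 34 genes passed by limma, 3 were higher and 5 lower at an unadjusted p under 0.05, and Ctsb and Sqstm1 were at 0.03 and 0.17 (adjusted p = 0.885 and 0.426; Ctsb -0.03 after centring). Camera put this group barely past the threshold as lower (adjusted p = 0.0492; adjusted p = 0.536 with an estimated correlation, 0.0914 with the block), although its median was 0.008 (-0.06 after centring) and its mean -0.02. It did not pass without naive replicate 2 (adjusted p = 0.252), ionomycin replicate 2 (0.0909) or 3 (0.221), nor after quantile normalization (0.299) or centring (0.163), among genes above background (0.175), with the block of 2 levels (0.0599) or by fry (0.847). Cholesterol synthesis (24 genes, 3 higher and 0 lower at an unadjusted p under 0.05), ribosome biogenesis (45 genes, 3 and 0) and glycolysis and hypoxia (30 genes, 2 and 2) had 0 members past the threshold by limma; over the list alone 0, 1 and 1 rose. Scd1 was at 0.60 (limma adjusted p = 0.166), Abcg1 at -0.16 (0.607), Npm1 at 0.01 (0.955), Ncl at -0.01 (0.973), Gapdh at -0.04 (0.772) and Pgk1 at 0.10 (0.699). Npm1 was at -0.05 after centring and Gapdh at 0.002 after quantile normalization. These 3 groups did not pass (camera adjusted p = 0.640, 0.306 and 0.631), and the ribosome biogenesis median of 0.003 turned to -0.06 after centring. Single arrays moved all 3 at camera's preset correlation of 0.01, although the correlations estimated over all arrays were far higher (0.543, 0.697 and 0.543). Without naive replicate 1, cholesterol synthesis rose (adjusted p = 0.00241), ribosome biogenesis rose (0.00143) and glycolysis fell (0.000215), whereas without naive replicate 3 cholesterol synthesis (0.0454) and ribosome biogenesis (0.00100) fell, the latter also without naive replicate 2 (0.0486). Without both replicate 1 arrays, cholesterol synthesis (0.0437) and ribosome biogenesis (0.0251) rose and glycolysis fell (0.0251), as it did with array weights (0.0173).

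Cell cycle genes differed more between replicates than between groups. In the G2/M list, 0 of 43 genes passed by limma, and 0 were higher or lower at an unadjusted p under 0.05, but 32 were lower at all 3 replicate numbers and the median was -0.44. Mki67, the proliferation marker, was at 10.53 ± 1.81 in naive and 9.63 ± 1.88 in ionomycin arrays (log2 -0.90 ± 1.20 SE, limma adjusted p = 0.716). With the replicate number as a block it fell (adjusted p = 0.0372), as did 2 other members, and 17 members fell when adjusted over the list alone. Ube2c, the other brightest member of the rule, was at -0.03 (adjusted p = 0.981). The replicate 1 arrays had higher G2/M transcripts than the mean of replicates 2 and 3, by a median of 2.50 in naive and 1.76 in ionomycin cells. In the list for G1/S and replication, 0 of 40 passed by limma, 0 were higher and 1 lower at an unadjusted p under 0.05, and 21 were lower and 4 higher at all 3 replicate numbers (median -0.28). With the block 1 rose and 11 fell when adjusted over the list alone. Its brightest members Ccnd2 and Cdk6 were at 0.19 and -0.27 (limma adjusted p = 0.424 and 0.221). For Cdk6 limma's adjusted p was 0.113 with the block and 0.0498 with the block of 2 levels. In this list replicate 1 stood higher by a median of 1.29 in naive and 0.71 in ionomycin cells.

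As groups, both cell cycle lists fell (camera adjusted p = 0.00149 for G2/M and 0.000960 for G1/S; adjusted p = 0.738 with an estimated correlation for either), but not by fry (adjusted p = 0.847 for either). With the replicate number as a block the adjusted p was 1.36e-16 for G2/M and 7.35e-09 for G1/S, and without both replicate 1 arrays, a setting chosen after seeing the data, it was 7.52e-11 and 0.000406, all lower. These values rest on camera's preset correlation of 0.01. With the block and an estimated correlation, neither list passed (camera adjusted p = 0.401 for G2/M and 0.519 for G1/S). G2/M did not pass after centring (adjusted p = 0.233) or without ionomycin replicate 2 (0.127) or 3 (0.109), nor G1/S after centring (0.123) or without ionomycin replicate 2 (0.0654), and without naive replicate 1 camera's direction was up for both (0.237 and 0.222).

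Marker lists of other cell types that a marrow culture could hold had 0 members past the threshold by limma in each case. Lymphocyte markers (17 measured, 11 above background, 3 higher and 0 lower at an unadjusted p under 0.05, 1 higher when adjusted over the list alone and 0 with the block) rose as a group (camera adjusted p = 0.00494, and 0.498 with an estimated correlation). The natural killer cell genes Ncr1 and Eomes were at 0.90 and 0.66 (limma adjusted p = 0.0794 and 0.396). For Ncr1 limma's adjusted p was 0.0976 with the block and 0.0334 with the block of 2 levels. Dendritic cell markers (14 measured, 9 above background, 6 and 0 at an unadjusted p under 0.05, 5 higher over the list alone and 3 with the block) rose as a group (camera adjusted p = 0.00394; adjusted p = 0.270 with an estimated correlation), with H2-Ab1 at 0.18 (adjusted p = 0.749). Stromal markers (14 measured, 9 above background, 3 and 0 at an unadjusted p under 0.05) rose as a group (camera adjusted p = 0.0392, and 0.498 with an estimated correlation). Pecam1 was at 0.39 (limma adjusted p = 0.267, 0.107 with the block and 0.0412 with the block of 2 levels) and Col1a1 at 0.18 (0.336). The stromal call ended after quantile normalization (0.185) or centring (0.0510) and without naive replicate 1 (0.0540) or 3 (0.0892) or ionomycin replicate 2 (0.0803) or 3 (0.0652).

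Markers of macrophages (19 measured, 3 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 0.512, and 0.0314, higher, without ionomycin replicate 3) and neutrophils (16, 1 and 0; 0.532) did not pass as groups. Neither did those of basophils and eosinophils (12, 2 and 1; 0.903), where over the list alone 1 rose and 1 fell, or of erythroid cells and megakaryocytes (8, 1 and 0; 0.532). The medians of the neutrophil and basophil lists, both 0.06, turned to -0.007 and -0.008 after centring. The brightest members of these 4 lists were Cd68 (-0.28, limma adjusted p = 0.756), Lyz2 (0.17, 0.897), Ly6g (-0.02, 0.928), Prtn3 (0.18, 0.253), Cd200r3 (-0.29, 0.165), Mcpt8 (0.09, 0.939), Itga2b (-0.06, 0.748) and Vwf (-0.23, 0.514). Of the mitochondrially encoded genes, mt-Rnr1 alone was measured, at -0.01 (0.941; 0.02 after quantile normalization).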

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

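All tests of the heat shock pattern, the test of array intensity for the replicate 1 arrays and the simulation of marker rises were chosen after the result was seen. The other tests here were fixed before it. Both tests for other cell types were set aside after their values were seen, and the test of dim rows was read with a margin that its rule did not hold.

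Rows outside the gene-level comparison also carried a signal. With all rows tested in limma, 7 rows that name several genes were higher after ionomycin, as were 23 rows without a gene name, and 6 rows without a gene name were lower. The largest rise was 2.79 on the log2 scale among rows with several names and 3.05 among those without one. They name no gene here, and which transcripts they measure was not analysed here.

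The first pattern is the rise of heat shock genes, whose median log2 difference was 0.73. Near-identical HSP70 copies that share probes cannot account for the whole, since the 16 members outside that family had a median of 0.831. Replicate 1 alone does not account for it either, since the medians at numbers 2 and 3 were 0.370 and 0.396, against 0.761 at number 1. A shift of all genes at this brightness is argued against by 0 of 10000 random lists matched on mean expression reaching the list's median (their highest was 0.199). A candidate explanation is therefore a response to the ionomycin treatment that the design names, as a hypothesis, because pattern and tests come from the same arrays; handling that differed between the groups was not recorded in the sources used here and stays open.

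The second pattern is that the replicate 1 arrays stood apart in both groups. Besides the cell cycle lists, glycolysis and hypoxia genes differed there by a median of -0.873 from the other naive arrays and of -0.223 from the other ionomycin arrays, with Egln3 at -3.33 and -1.22, and cholesterol synthesis genes were higher (0.738 and 0.519). A trend on mean expression, which array intensity or normalization could leave, does not account for the G2/M gap. Once that trend was removed, G2/M genes were still 1.83 higher in the group where the gap was smaller. G2/M had the largest gap of the lists compared. The glycolysis and hypoxia median was then -0.90 in naive and -0.27 in ionomycin arrays. Array effects that do not follow mean expression were not tested and stay open. Cells of another type in the replicate 1 cultures stay open: the smaller of each marker list's 2 medians was at most 0.0818 (7 basophil and eosinophil markers above background), but such a median decides nothing where members go apart, and Mcpt8 (1.24 in naive and 1.48 in ionomycin arrays) and Prss34 (1.54 and 1.98), the latter chosen after its values were seen, were higher in replicate 1 while Cd200r3 differed by 0.14 and -0.02. No group in the design covers this split, so apart from a mix of cell types no biological explanation was tested, and differences in culture density, age or medium stay open.

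The third pattern is the small rise of lymphocyte, dendritic cell and stromal markers. For a shift of dim rows, the 16 markers below background had a median 0.0667 above that of the chemosensory receptor genes. By the rule set beforehand, a bound of 0.05, this argues against such a shift. The excess over the bound is less than the standard error of their mean (0.0214), a margin outside that rule, so it decides little. Among genes above background the 3 lists still rose (camera at its preset correlation, adjusted p = 0.0102, 0.0108 and 0.0398). That filter kept every gene whose mean in either group lay above background, so a dim marker that rose could stay in. It therefore cannot show whether dim rows account for the rise of these lists. Some markers lie just above background (Siglech at 6.03 in naive arrays), so a shift of such rows stays open too. Other cell types in the ionomycin cultures stay open too: 0% of the 29 markers above background passed the threshold, but in simulated arrays the same markers were called in 0% of cases when raised by their median of 0.17 and in 87.6% when raised by log2 1, so the test bears on large rises and not on ones this small (with the block of 2 levels 3 of the 29 passed). All 29 had a fitted difference above 0 as deposited, among them Ncr1 (0.90 ± 0.14), Eomes (0.66 ± 0.37) and, chosen after their values were seen, Itgax (0.67 ± 0.18) and Irf8 (0.32 ± 0.07). This depends on the scaling: the median of all genes above background was itself 0.05, and Bst2 turned to -0.003 after centring. Eomes was lower at replicate number 1 (-0.20) and higher at numbers 2 and 3 (1.09 and 1.11). Of these lists' members, 2 dendritic and 1 stromal marker are also in another list, and 11, 9 and 9 lie above background in these cultures.

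The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes higher (87, highest other split 0), genes lower (18, highest other 0), genes at least 2-fold higher (39, highest other 0) and lower (1, highest other 0), 1 of the 10 splits, the real one, gave a count as high. At an unadjusted p under 0.05 the real split gave 4699 genes and the highest other 3823. For lists that rose, 2 of the 10 splits gave as many as the real 13 (highest other 15), and for lists that fell, 4 gave as many as the real 6 (highest other 9). Of the splits that part all 3 replicate numbers, the other 3 gave 0 genes in either direction, between 3 and 7 lists that rose and between 1 and 6 that fell. Every other split still sets 2 arrays of 1 treatment against 1, so part of any treatment effect stays in it, and the list calls of those splits do not separate treatment from other differences between arrays.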

How the results depend on the processing

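Leaving out both replicate 1 arrays, the block of 2 levels and the block joined to an estimated correlation were chosen after seeing the data; all other settings were planned. Of the 39 named genes past the threshold, 0 changed sign in any setting, but most settings fixed this in advance. Their groups did not overlap, so leaving out or weighting arrays could not turn the sign. Only another scaling or the mean of a gene's rows could have done so. All 39 lost the call under the t statistic without moderation. Of the genes that did not pass, 22 changed sign in some setting. The counts of calls moved between settings, and except where noted the cause of these moves was not tested.

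The replicate block gave 33 genes lower, 62 at least 2-fold higher and 2 at least 2-fold lower; 13 named genes lost the call and 5 gained it, and it ended the calls of 2 lists (calcium and NFAT, lysosome) and no other. Centring gave 32 genes lower and 2 lists that fell. Trend and robust settings gave 9 genes lower, as did testing all rows, where more rows share the adjustment. Array weights, lowest for naive replicate 1 (0.246) and ionomycin replicate 1 (0.416), gave 2240 genes higher, 1654 lower, 118 at least 2-fold higher and 9 lower. The t statistic without moderation gave 0 genes in all 4 counts (smallest adjusted p = 0.0738), with 3258 higher and 1318 lower at an unadjusted p under 0.05. Leaving out both replicate 1 arrays gave 423 higher, 429 lower, 102 at least 2-fold higher and 10 lower, and the block of 2 levels gave 677, 744, 109 and 5. An estimated correlation in camera left 0 lists that rose and 0 that fell, also with the block (3 and 0 at an unadjusted p under 0.05), and fry left 2 that fell.

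Leaving out each array in turn gave 1 to 95 genes higher, 0 to 55 lower, 1 to 54 at least 2-fold higher and 0 to 8 at least 2-fold lower, 10 to 14 lists that rose and 2 to 8 that fell. Genes higher and lower were 95 and 55 without naive replicate 1, 13 and 0 without naive replicate 2, 8 and 1 without naive replicate 3, 35 and 0 without ionomycin replicate 1, 1 and 0 without ionomycin replicate 2, and 7 and 0 without ionomycin replicate 3. At an unadjusted p under 0.05 these fits held between 1655 and 3355 genes higher and between 1069 and 2269 lower. Lists that fell numbered 2 without ionomycin replicate 2 and 3 without ionomycin replicate 3.

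Signal over background limits 9 of the 87 genes called higher, whose naive mean lay below background, so the size of their differences is uncertain. Testing only genes with a mean above background in either group gave 97 higher and 20 lower. Of the 87 genes, 86 were among these 97, so the filter does not address the limit for genes dim in naive arrays.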

Other observations

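All genes in this part were chosen after their values were seen. Of the 87 genes called higher, 62 were in no list, as were all 18 called lower. Several encode receptors or surface proteins: Havcr2, which encodes TIM-3, rose by 0.94 ± 0.07 on the log2 scale from an already high 12.31 (limma adjusted p = 0.0153), Tigit rose by 1.33 ± 0.10 (0.0153) and C5ar2, a receptor for complement C5a, by 1.34 ± 0.14 (0.0277). Ceacam1 and its close paralog Ceacam2, whose sequences are similar enough that probes may cross-hybridise, rose by 1.66 ± 0.13 and 1.65 ± 0.11 (0.0153 and 0.0114). Among regulators, Zfp57, an imprinting factor, rose by 1.96 ± 0.13 (0.0114), the aryl hydrocarbon receptor gene Ahr by 0.69 ± 0.05 (0.0153) and Irf4 by 0.91 ± 0.11 (0.0436). The carbonic anhydrase gene Car2 rose by 1.61 ± 0.08 (0.00363), the glutathione transferase gene Gstm1 by 1.27 ± 0.13 (0.0277), and Aldh18a1, an enzyme of proline synthesis, by 1.02 ± 0.09 (0.0176).

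The mitochondrial chaperonin genes Hspd1 and Hspe1 rose with the cytosolic chaperones, by 1.24 ± 0.11 and 1.00 ± 0.07 (limma adjusted p = 0.0176 and 0.0114), as did Dnaja4, outside the list, by 1.15 ± 0.06 (0.00549). Gm2663 and its neighbour on chromosome 6, 1810009J06Rik, also rose (limma adjusted p = 0.0153 for both). Gm2663, which the naming rule leaves out, had the largest fitted rise of all called genes (log2 4.61), next to that of Rln3 (4.60). The naive means of Gm2663 and 1810009J06Rik lay below background (5.90 for Gm2663), so the size of their rise is uncertain. Whether these neighbours share probes was not tested. With the replicate block, the G2/M genes Kif11 and Top2a also passed, lower by -1.02 and -0.77 (adjusted p = 0.0231 and 0.0330).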
